A study of Mus musculus with 6 samples.

How the data were processed

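Expression was measured in 6 tumour RNA samples, 3 labelled control and 3 labelled treated, on the mouse PanCancer Immune Profiling panel of the nCounter platform, which counts single RNA molecules by hybridising each to a pair of probes that carry a fluorescent barcode, with no amplification. Groups and replicate numbers were taken from the sample titles. The labels give 6 as the number of mice without saying that each sample came from a different one, so p-values measure the spread between these samples. What the control mice received is not given in the sources used here.

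The deposited raw table holds a count of barcodes per probe and sample, per the file headers, with no scaling. It marks 750 probes as endogenous and 20 as housekeeping, where the labels' protocols give 730 immune and 40 housekeeping genes; the total of 770 is the same in both. It also holds 6 positive and 8 negative control probes. The deposited series table holds a normalized score per gene, and comparison with the raw table showed what the authors computed: each of the 770 values in every sample lay within 1 of the raw count multiplied by a sample factor that brings the geometric mean of the 20 housekeeping probes to a common level. The software and version behind either table are not given in the sources used here. Probes were named by the symbols in the file. Of the 770 transcript identifiers, 746 matched the mouse RefSeq table of assembly GRCm38.p6, used for names only, and 9 of these carry a different current symbol (Emr1 is now Adgre1). Ccl27a, Ccl19 and Raet1 have near-identical copies in the mouse genome, and which copies a probe reads is not stated, so their counts may include those copies.

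The main comparison was fitted to the raw counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, glmQLFit and glmQLFTest). Sample scaling used the geometric mean of the 20 housekeeping probes, each of which had a mean raw count of at least 50. Genes entered the test with a mean raw count of at least 20 over the 6 samples, which left 548 and set aside 222. P-values are two-sided and Benjamini-Hochberg adjusted over the 548 genes, with a threshold of 0.05. Fold changes are treated over control on the log2 scale with the standard error (SE) derived from the F statistic, and levels are housekeeping-scaled counts as mean ± SD over 3 samples. The common dispersion was 0.0457.

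Lists of genes for 32 pathways and cell types with at least 3 tested members were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01 and adjusted over the 32 lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance in 1 direction, were run beside it. The T cell list holds Cd3eap, which encodes a subunit of RNA polymerase I and is no T cell marker. Samples, groups, lists, tests, the rule for named genes and the alternatives in scaling, filtering, background, test, blocking and left-out samples were chosen before the data were examined. The rule for named genes took the 12 genes of largest change in each direction among those past the threshold with no overlap between groups, filled to 12 by lowest p where fewer passed, the 2 members of lowest p from each list, and 11 measured genes of a fixed set: Cd274, Pdcd1, Ctla4, Cd8a, Cd4, Foxp3, Ifng, Gzmb, Il6, Tnf and Arg1. The same set included Mki67, Sirt1, Sirt3, Tyr and Pmel, for which no value is reported. Some genes that this rule takes are not reported here, although they stay in the tests, counts and list medians. All other genes named were chosen after their values were seen.

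Total counts over the 770 genes were 322485, 472402 and 362999 in the control samples and 254862, 170729 and 118221 in the treated samples. The counting error of a gene therefore differs between groups, and the test takes it into account through the raw counts. Replicates of 1 group differed by more than counting noise, with a chi-square per degree of freedom of 6.32 to 20.4 over the 6 pairs, and none was treated as a duplicate. The test was tested on simulated data with the samples' own means and totals (20 data sets, 200 changed genes each, a mean of 546 genes tested). It recovered 31.2% of genes changed 1.5-fold, 81.6% of those changed 2-fold and 99.5% of those changed 3-fold, with 2.89% of calls on unchanged genes. A list shifted as a whole was called in all 20 sets, and 1 of 540 tests of unshifted lists was called. The simulated genes were drawn independently of each other at the common dispersion. The gene rates therefore hold for independent genes of that spread with 200 changed, and not for genes that vary more between samples. The list rates do not cover correlated members, and the correlation estimated in the 3 lists called in the data was 0.13 to 0.26.

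Alternatives were scaling by TMM, median of ratios, total count, positive control probes or the median housekeeping ratio, no count minimum, a minimum of 50, a minimum set by the negative probes (mean plus 2 SD), subtraction of the negative probe mean, DESeq2 1.42.0, limma on log2 of the scaled counts and of the deposited score (pseudocount 1), the replicate number as a block, and each sample left out in turn. Thinning of all samples to the lowest total, and leaving samples out with the count minimum of all 6 kept for named genes that would fall below it, were added after seeing the data. Plots were drawn with matplotlib 3.10.9.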

Results

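The samples were tumours of a genetically engineered melanoma mouse, in which 4-hydroxy-tamoxifen painted on the shaved back at 10 weeks of age starts tumours that carry an activated Braf allele. Tumours of 3 control samples were set against 3 from mice given 4′-bromo-resveratrol (4′-BR) at 30 mg/kg by intraperitoneal injection on 3 days a week for 5 weeks. 4′-BR is a bromine-bearing analogue of resveratrol described as an inhibitor of the deacetylases Sirt1 and Sirt3. The comparison asks how treatment altered the expression of immune genes in the tumours.

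Treated samples gave lower counts than control samples. Total counts were 386000 ± 77550 in control and 181300 ± 68930 in treated samples (mean ± SD, n = 3 each), a ratio of 2.13, with no overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 samples can give). The housekeeping probes followed, with geometric means of 590 ± 99.2 and 308 ± 112. The positive control probes, which carry a fixed amount of synthetic RNA, had geometric means of 689 ± 59.7 and 557 ± 153 (exact permutation p = 0.3). Depth and treatment could not be separated by any grouping of the samples. After housekeeping scaling the negative probes stood at 4.63 ± 0.45 in control and 5.60 ± 2.03 in treated samples.

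**Figure D1:**
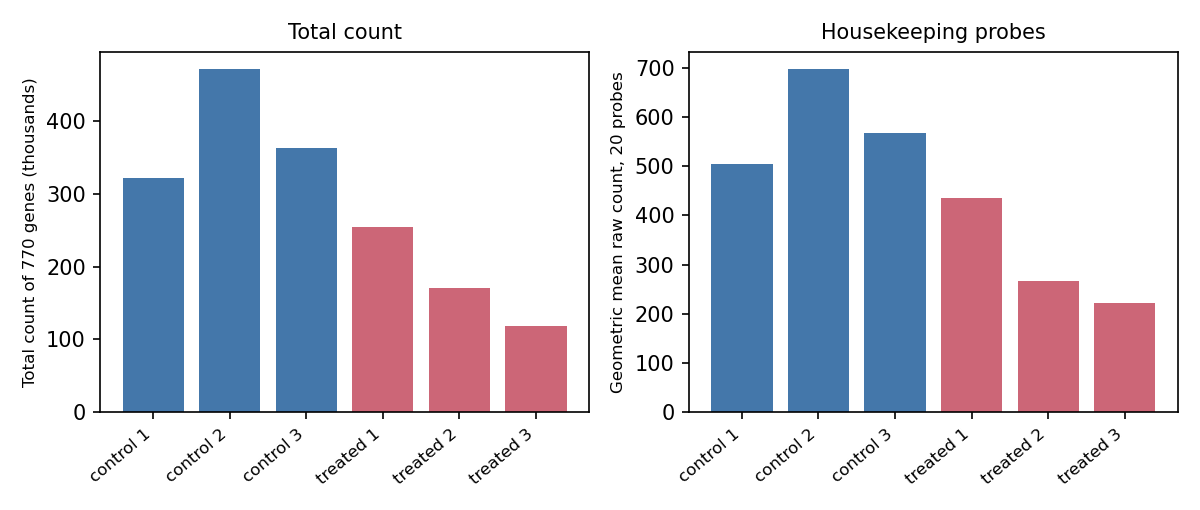
Total raw count of the 770 genes (left, axis in kilocounts) and geometric mean raw count of the 20 housekeeping probes (right) in each of the 3 control (blue) and 3 treated (red) samples, 1 bar per sample. Totals run from 322485 to 472402 in control and from 118221 to 254862 in treated samples.

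Lower in treated tumours were 5 of 11 genes of the stroma list, 4 of 18 of the macrophage list and 8 of 20 of the complement list, as were Il1b and Nlrp3, and a smaller set of 7 genes that includes Xcl1 and Il12rb2 was higher. The 3 lists passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.807 with an estimated correlation for each) or with fry. Fn1, which encodes the matrix protein fibronectin, fell 3.12-fold, from 2059 ± 452 to 661 ± 35.2 scaled counts (n = 3 each, log2 fold change −1.64, SE 0.19, edgeR adjusted p = 0.00422). Il1b, the gene of the inflammatory cytokine interleukin-1β, fell 5.77-fold from 113 ± 59.2 to 19.1 ± 7.02 (adjusted p = 0.0356). The rise was led by Il12rb2, a subunit of the interleukin-12 receptor, at 22.9 ± 4.14 and 54.2 ± 8.24 (2.36-fold, adjusted p = 0.0387), and by Xcl1, a chemokine of natural killer and activated T cells, at 23 ± 5 and 51.7 ± 6.36 (2.22-fold, adjusted p = 0.0402).

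Of 548 genes tested, 38 passed the threshold, 7 higher and 31 lower in treated tumours, and 128 had an unadjusted p under 0.05 (42 higher, 86 lower). In all 38 the 3 treated samples lay on 1 side of the 3 control samples. This held for 167 of the 548 genes (30.5%), where chance gives 10% on average over all splits of the samples. The share in the other splits was not computed, so an excess was not tested. The median log2 fold change of all tested genes was −0.04, and the difference of the per-sample medians was within their spread (exact permutation p = 0.7). The first principal component held 46.9% of the variance and separated the groups, with control samples between −8.17 and −2.76 and treated samples between 4.51 and 8.29.

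The balance of calls moved with scaling, to 16 higher and 38 lower with TMM, 17 and 37 with median of ratios, 30 and 30 with total count, where the median of all genes moved to 0.12, and 1 and 243 with positive control probes, where it moved to −0.67. All called genes that could be tested kept their sign when single samples were left out, which follows from their groups not overlapping. The count fell to 1 without control 1, 7 without control 2 and 1 without treated 3, and in edgeR to 0 without treated 1 (107 genes at an unadjusted p under 0.05) or treated 2 (117), while 36 passed without control 3.

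**Figure D2:**
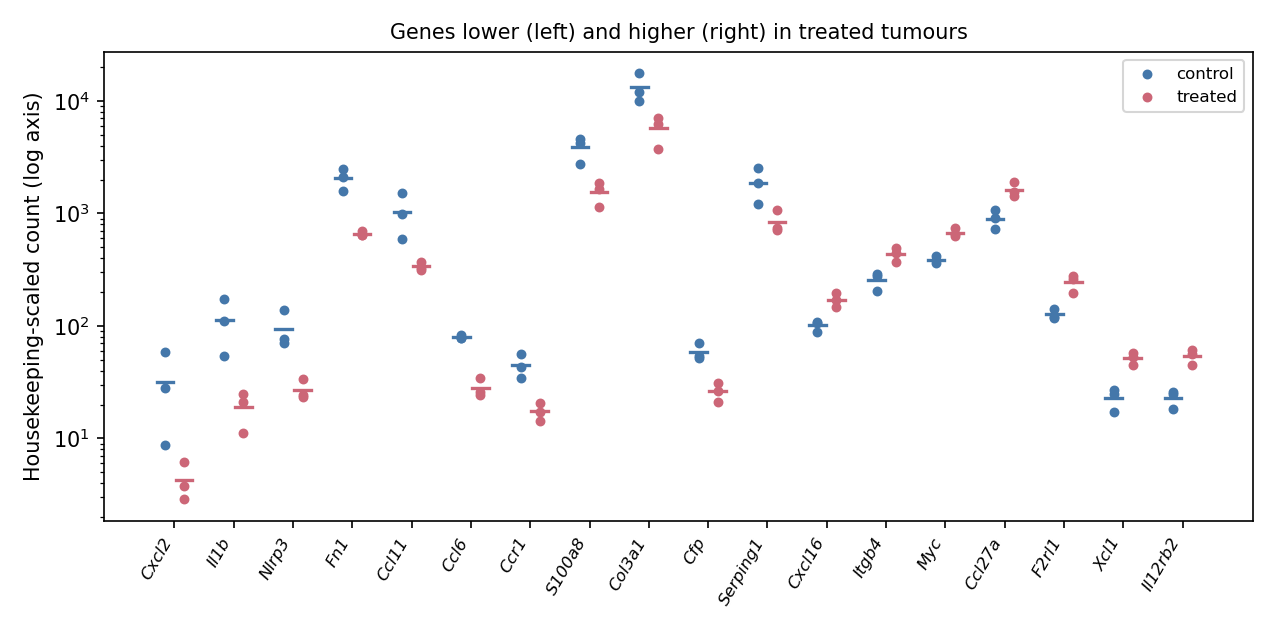
Housekeeping-scaled counts (log axis) in the 3 control (blue) and 3 treated (red) samples of genes with the largest falls and the 7 genes that rose, points for samples and lines for group means. The groups do not overlap for any gene shown, as for Fn1 with means of 2059 and 661.

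The fibroblast and stroma list fell as a group. Of its 11 tested members, 5 fell over all genes tested and 8 adjusted over the list alone, with a list median of −0.70 (camera adjusted p = 0.000273, and adjusted p = 0.807 with an estimated correlation). The 5 were Fn1, the fibrillar collagen genes Col3a1 (13230 ± 4032 to 5692 ± 1723, log2 fold change −1.22) and Col1a1 (11210 ± 1925 to 6190 ± 1084, −0.86), the fibroblast protease Fap (−0.93) and Ccl11, the eosinophil chemokine eotaxin (1028 ± 463 to 338 ± 28.6, −1.61). Not every member was lower, since Vim was at 0.26, Cfd at 0.57 and Cxcl12 at 0.07, none past the threshold, and all 3 were negative with positive control scaling. In the adhesion and metastasis list 5 of 39 members fell and 1 rose (7 and 2 adjusted over the list alone), with a median of −0.23 (adjusted p = 0.204). Besides Fn1 and Itgam these were Plau, the urokinase protease (−0.87), Thbs1, thrombospondin-1 (−0.72), Itgb1, the integrin β1 chain (−0.71), and the riser Itgb4. Thbs1 was also the member that fell, over all genes and adjusted over the list alone, among 15 angiogenesis genes (median −0.34, adjusted p = 0.214) and 11 genes of TGF-β signalling (median −0.21, adjusted p = 0.379). Angpt2, a vessel-destabilising ligand, was at −1.15 (adjusted p = 0.0708) and Smad4 at −0.26 (adjusted p = 0.399). No endothelial gene of 9 passed either adjustment (median −0.23, adjusted p = 0.329), with Tie1 at −0.67 and Mcam at −0.59.

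All 18 tested macrophage and monocyte genes had negative fold changes, with a median of −0.55 (camera adjusted p = 0.000273, and adjusted p = 0.807 with an estimated correlation). The test was passed by 4 of them, over all genes and adjusted over the list alone. They were Itgam, the CD11b integrin chain (87.2 ± 13.9 to 40.2 ± 5.65, −1.12), the complement C1q chains C1qb (582 ± 145 to 291 ± 33.1, −0.999) and C1qa (−0.91), and the mannose receptor Mrc1 (382 ± 32.7 to 230 ± 32.2, −0.73). General macrophage genes were closer to 0 and did not pass, with Csf1r at −0.53, Emr1 at −0.37, Fcgr1 at −0.35 and Cd68 at −0.13 (SE 0.22), the last turning to 0.01 with total count scaling or thinned counts and to 0.06 without treated 3. Arg1, the arginase of suppressive macrophages, was at −0.45 (adjusted p = 0.31).

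The complement list, which shares Itgam, C1qa and C1qb with the macrophage list, had a median of −0.83 over 20 tested members (camera adjusted p = 0.00101, and adjusted p = 0.807 with an estimated correlation). Of these, 8 fell over all genes tested, and 11 fell and 1 rose adjusted over the list alone. The falls took in both activators and inhibitors of the cascade: properdin, Cfp, which stabilises the alternative pathway convertase (58.5 ± 10.1 to 26.1 ± 5.04, −1.18), the C1 inhibitor Serping1 (1870 ± 659 to 842 ± 199, −1.15), the protease C1ra (−1.14) and the scavenger collectin Colec12 (−1.03). The inhibitor Cd55, the 1 that rose over the list alone, was at 0.63 (adjusted p = 0.0708 over all genes), and C2 at 0.71, both slightly negative with positive control scaling.

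The largest fall among genes that passed was that of Cxcl2, a neutrophil chemokine, from 31.9 ± 25.3 to 4.28 ± 1.74 (log2 fold change −2.94, SE 0.76, adjusted p = 0.0481), where the treated level was no higher than that of the negative probes, so its size is loosely set. Without control 2 it was at −2.11 and no longer passed (adjusted p = 0.087). Nlrp3, the sensor of the inflammasome that matures interleukin-1β, fell from 94.5 ± 37.3 to 27.1 ± 5.56 (−1.78, adjusted p = 0.0356). S100a8, an abundant neutrophil and keratinocyte calgranulin, fell from 3879 ± 983 to 1544 ± 368 (−1.33). It was the 1 of 6 neutrophil genes to pass, over all genes and adjusted over the list alone (list median −0.62, adjusted p = 0.504), and Csf3r, the receptor for the neutrophil growth factor G-CSF, was at −1.19 (adjusted p = 0.177), and at −0.45 without control 2. Il1b was likewise the 1 of 10 interleukin genes to pass under both adjustments. That list had a median of 0.11, a mean of −0.16 and an upward test direction (adjusted p = 0.86), and Csf1 was at 0.31.

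Chemokine ligands moved both ways. Of 26 tested, 4 fell and 3 rose (8 and 6 adjusted over the list alone), and the list as a whole did not pass (median −0.21, adjusted p = 0.86). Ccl6 fell from 79.2 ± 2.97 to 28.1 ± 5.31 (−1.49), and the monocyte attractant Ccl8 fell from 1734 ± 208 to 1035 ± 116 (−0.74), beside Ccl11 and Cxcl2. Xcl1, Ccl27a and Cxcl16 rose. Among 10 chemokine receptors Ccr1, a receptor of monocytes and neutrophils, fell under both adjustments (44.6 ± 11.2 to 17.4 ± 3.16, −1.39), with a list median of −0.47 (adjusted p = 0.588). Lbp, which hands bacterial lipopolysaccharide to CD14, fell (137 ± 40.1 to 68.6 ± 4.91, −0.99), and no gene of the 26 in the Toll-like receptor list passed adjusted over the list alone (median 0.00, mean −0.18, adjusted p = 0.811, Cd180 at −0.67). The mast cell chymase Cma1 fell (456 ± 70.3 to 256 ± 42.9, −0.83) under both adjustments, with Kit at 1.04 (adjusted p = 0.244, and 0.28 without treated 2) and a median of −0.30 over 3 tested mast cell and eosinophil genes (adjusted p = 0.671). Outside the lists, Lyz2, the lysozyme of myeloid cells, fell by 1.00 on the log2 scale, the clotting factor subunit gene F13a1 by 0.96, the Src-family kinase genes Lyn by 0.86 and Fyn by 0.72, and the junctional adhesion gene Jam3 by 1.12.

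The 7 genes that rose were led by Il12rb2 and Xcl1. F2rl1, a protease-activated receptor of epithelium, rose from 127 ± 13.7 to 244 ± 44.6 (log2 fold change 0.95), Ccl27a, a T cell attractant made by keratinocytes, from 901 ± 179 to 1621 ± 245 (0.85), Itgb4, the integrin chain that anchors basal keratinocytes, from 258 ± 46.4 to 436 ± 59.8 (0.76), and Cxcl16, which attracts CXCR6-bearing lymphocytes, from 101 ± 11.2 to 171 ± 24.4 (0.76). The growth regulator Myc rose from 389 ± 29.2 to 673 ± 59.7 (0.79, adjusted p = 0.0356). With positive control scaling none of the 7 passed, at values from 0.13 to 0.62, against a median of −0.67 for all genes. Among genes that the rule took and that did not pass were Ccl1 at 1.33, with an adjusted p of 0.05 that lay just above the threshold, Egr3 at 0.61 (0.0511), Psen2 at 0.76 (0.0626) and Il22ra1, a receptor chain for interleukin-22, at 0.85 (0.0635). Egr3 turned to −0.01 with positive control scaling.

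The lists that hold these genes did not pass as a whole. Of 9 keratinocyte and epithelial genes, Itgb4 rose over all genes, 2 rose and 1 fell adjusted over the list alone, and the median was 0.05 (adjusted p = 0.554), with Cxcl14 at −0.58. Myc was the 1 of 6 proliferation genes to pass under both adjustments, with a list median of −0.03, a mean of 0.04 and an upward test direction (adjusted p = 0.588), and Ccnd3 at −0.43. Il12rb2 was the 1 of 27 interleukin receptor genes under both (median 0.13, adjusted p = 0.268). None of 25 MAPK genes passed either adjustment (median 0.02, mean −0.02, upward test direction, adjusted p = 0.588), with Creb1 at −0.61. The 4 melanocyte genes had a median of 0.09 (adjusted p = 0.86), none past either adjustment.

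T cell, cytotoxic and natural killer cell lists had positive medians and did not pass. Of 9 genes in the T cell list 7 were positive, with a median of 0.41 (camera adjusted p = 0.121) and none past either adjustment. The list passed upward with no count minimum, with the minimum set by negative probes, with positive control scaling and with limma on log2 values. The T cell kinase Zap70 was at 0.90 (20.6 ± 5.86 and 37.95 ± 6.87, adjusted p = 0.111), Cd3d of the T cell receptor complex at 0.58 (adjusted p = 0.245), Cd4 at −0.15 (adjusted p = 0.773), and Cd3eap, no T cell gene, at 0.21. In the natural killer cell list Xcl1 was the 1 of 5 to rise under both adjustments (median 0.60, adjusted p = 0.229). None passed either adjustment among 3 cytotoxic genes (median 0.65, adjusted p = 0.204, Ctsw at 0.65 and Klrk1 at 0.68), 5 regulatory T cell genes (median 0.26, adjusted p = 0.268, Ikzf2 at 0.73 and Ccr4 at 0.56) or 5 B cell genes (median −0.31, adjusted p = 0.977, Blnk at 0.36 and Cd200r1 at −0.40). Cd3d, Ctsw, Ccr4 and Blnk turned negative with positive control scaling. Counts lay under the minimum for Cd8a (5.48 ± 1.89 in control and 7.20 ± 2.29 in treated samples), Foxp3 (11.4 ± 5.60 and 16.4 ± 5.35), Gzmb (4.32 ± 1.45 and 9.52 ± 3.13), Ifng (2.67 ± 1.32 and 6.05 ± 2.76), Pdcd1 (16.04 ± 6.59 and 13.3 ± 4.86), Il6 (13.5 ± 5.44 and 9.44 ± 4.33) and Tnf (15.3 ± 1.72 and 15.1 ± 3.71). After the same scaling the negative probes stood at 4.63 ± 0.45 in control and 5.60 ± 2.03 in treated samples. Cd8a, Gzmb and Ifng thus lay near background, and the size of their change is loosely set. In the fit with no count minimum none of these genes under the minimum passed over 770 genes. Gzmb, whose groups did not overlap, was at 1.08 (SE 0.45, adjusted p = 0.193), Ifng at 0.96 (SE 0.58), Foxp3 at 0.48 (SE 0.43), Cd8a at 0.30 (SE 0.47), Pdcd1 at −0.25 (SE 0.42), Il6 at −0.54 (SE 0.46) and Tnf at −0.01 (SE 0.34), adjusted p from 0.379 to 0.984 for the last 6.

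Checkpoint, interferon and antigen presentation genes did not pass as lists or as single genes, over all genes or adjusted over the list alone. Cd274, which encodes PD-L1, was at 53.5 ± 16.5 and 76.3 ± 12.4 (0.51, adjusted p = 0.305) and Ctla4 at 41.2 ± 15.0 and 43.8 ± 20 (0.06, SE 0.39, adjusted p = 0.929). Medians were 0.05 over 17 checkpoint genes (mean −0.01, upward test direction, adjusted p = 0.588), with Lgals3 at 0.51 and Cd47 at 0.34, 0.23 over 11 interferon-γ genes (adjusted p = 0.232), and −0.17 over 21 type I interferon genes (adjusted p = 0.86), with Ifitm2 at −0.58 and Irf7 at −0.88. They were 0.21 over 14 MHC class I genes (adjusted p = 0.268), with Tap1 at 0.62 and H2-M3 at −0.75, and 0.07 over 11 MHC class II genes (adjusted p = 0.588), with Ciita at 0.63 and Ctss at 0.34. No gene passed either adjustment in the NF-κB list (18 genes, median 0.13, adjusted p = 0.268, Ikbkb at 0.41 and Traf2 at 0.36), the TNF superfamily (13, median −0.10, adjusted p = 0.86, Tnfsf10 at 1.25 and Tnfrsf1b at −0.55), apoptosis (18, median 0.15, adjusted p = 0.588, Txnip at −0.46) or dendritic cells (10, median −0.31, adjusted p = 0.588, Cd83 at −0.61 and Clec4n at −0.85). Cd274, Ctla4, Lgals3, Cd47, Ciita, Ctss, Ikbkb, Traf2 and Csf1 turned negative with positive control scaling, and Ctla4 also with thinned counts.

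Over the 32 lists, 3 passed with the preset correlation, 0 with an estimated correlation (lowest adjusted p 0.807) and 0 with fry (lowest adjusted p 0.109). The preset calls of the stroma, macrophage and complement lists held without each sample in turn and under each of the 5 other scalings. Camera sets a list against the other genes, and scaling moves all genes of a sample alike. The scalings were therefore a weak check of these calls.

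**Figure D3:**
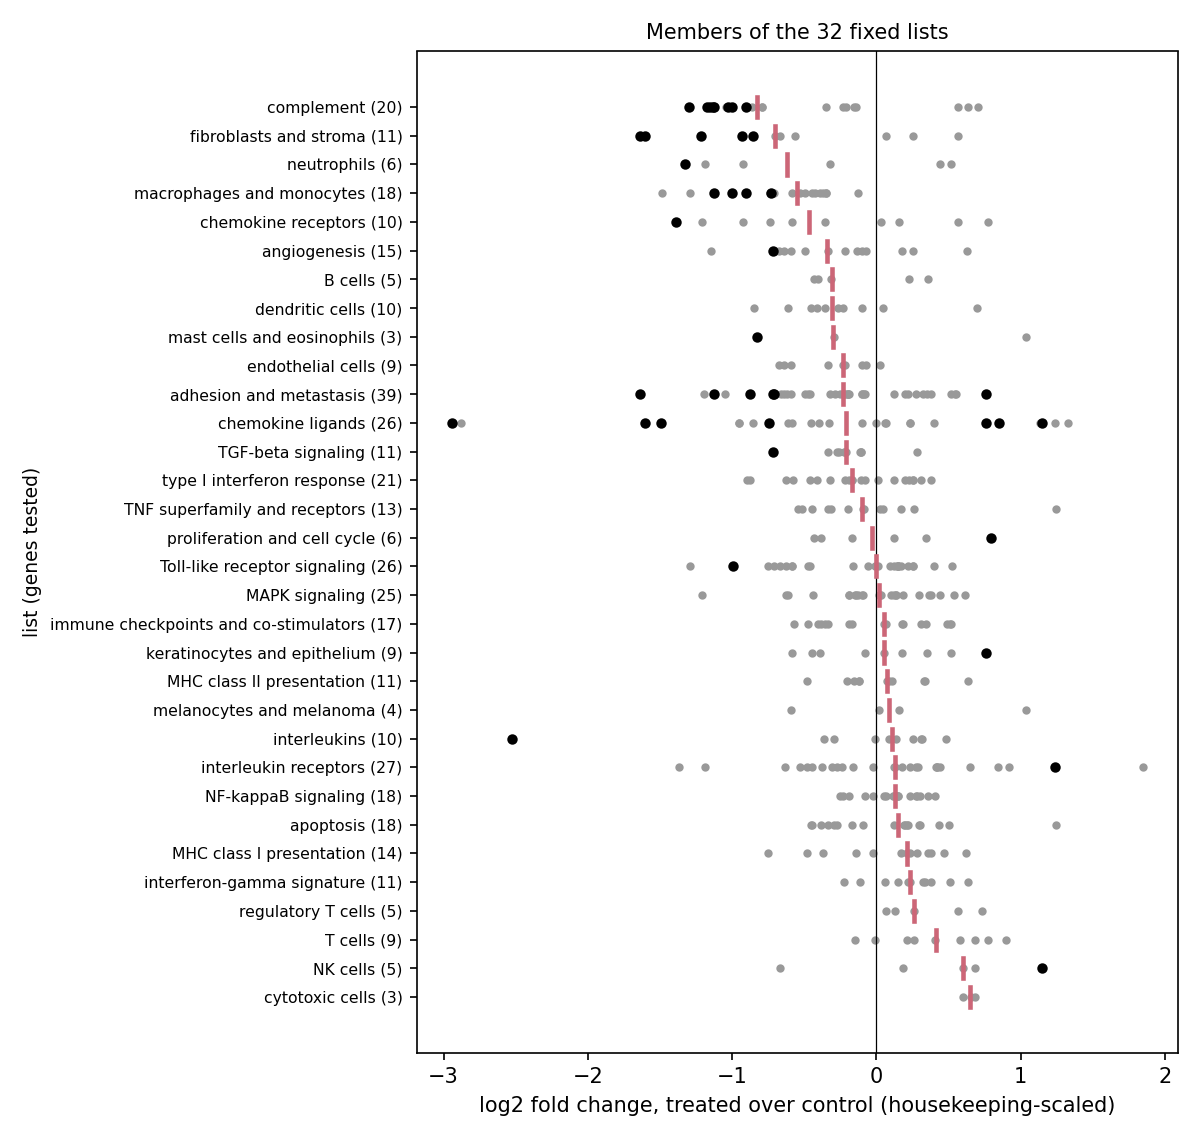
Log2 fold change (treated over control) of each tested member of the 32 lists, with the number of tested genes in brackets, black points for genes past the threshold and red lines for list medians. The complement, stroma and macrophage lists lie to the left with medians of −0.83, −0.70 and −0.55.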

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

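The tests of low counts, of scaling, of fibroblasts, of neutrophils, of epidermis and of the split for genes were chosen after the result each measures was seen, and those of macrophages, of a single control tumour and of the split for lists before. The choice of the genes in the next sentences also followed their values. Means of gene sets with an SE are differences of per-sample means of log2(scaled count + 1), which can depart from the mean of the edgeR fold changes.

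Among the probes below the minimum count, 12 stood above background (negative probe mean plus 2 SD) in every treated sample, and 3 of them also stood above every control sample after housekeeping scaling. They were Cd5, a T cell surface receptor, at 7.96 ± 2.38 in control and 19.4 ± 6.07 in treated samples (log2 fold change 1.20, SE 0.40, edgeR adjusted p = 0.104 over 770 genes), Tnfrsf4, the co-stimulatory receptor OX40, at 13.3 ± 5.88 and 25.6 ± 3.58 (0.94, SE 0.37, adjusted p = 0.18), and Ccr9, a homing receptor of gut lymphocytes, at 14.9 ± 1.07 and 23.3 ± 5.28 (0.61, SE 0.33, adjusted p = 0.328). In the other direction, 10 of 40 such probes above background in every control sample stood above every treated sample. None of the 3 passed. The order rests on the scaling for all 3, since raw counts in control and treated samples were 8, 18 and 9 against 13, 15 and 12 for Cd5, 10, 20 and 27 against 26, 19 and 12 for Tnfrsf4, and 19, 23 and 21 against 18, 17 and 14 for Ccr9.

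The lower values of the stroma, macrophage and complement lists, whose calls are lost with an estimated correlation (adjusted p = 0.807) and with fry, went with lower counts in the treated samples. The fall was not confined to probes with low counts, since the 25 members above the median raw count had a median of −0.74 (95% bootstrap interval over genes −1 to −0.45). These lists were picked for their fall, and a difference that goes with depth could lower abundant probes too, so this value cannot test it. The fall did not hinge on housekeeping scaling as against TMM, median-of-ratios or total count scaling, under which the median of the 45 members lay between −0.71 and −0.55. These scalings left the median of all tested genes at −0.055, −0.028 and 0.116, against −0.038 with housekeeping scaling. They therefore cover small changes of scale only. Positive control scaling moved the median of all genes further down, to −0.674. Fewer fibroblasts may contribute, as Col1a1, Col3a1, Pdgfrb and Fap had a mean of −0.95 (SE 0.24, edgeR mean −0.93). No spread was detected between these genes (heterogeneity p = 0.61, chi-square over genes). They were picked after their values were seen, so an even fall cannot be read for the stroma list. Its other members ranged from Fn1 at −1.64 to Cfd at 0.57, and Cxcl12 at 0.07 and Vim at 0.26 did not fall either. Fewer macrophages cannot be told apart from lower levels per cell, because the mean of Cd68, Csf1r, Emr1 and Fcgr1, −0.39 (SE 0.15, edgeR mean −0.34), lay between the values either would give. An effect of treatment on these cells stays open, as does any unmeasured difference between the tumours that goes with depth.

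Il1b, Cxcl2 and Nlrp3 had the largest falls among genes past the threshold, and their control levels varied widely. The mean of the 3 genes ranged from −2.73 to −1.86 when each control sample was left out and the tested genes were kept. The value of −1.86 is that without control 2, with Il1b at −2.08, Cxcl2 at −2.11 and Nlrp3 at −1.40. The 3 were picked for large falls with no overlap between groups, so a fall without any single control was largely fixed by that choice. Cxcl5 and Trem1, which did not pass, moved from −2.88 and −2.30 to −0.73 and −0.91 without control 2. A single inflamed control tumour therefore stays open as a contributor, although the fall of the 3 genes did not rest on control 2 alone. Fewer neutrophils cannot be told apart from lower levels per cell, as Csf3r and Cxcr2 had a mean of −0.93 (SE 0.47) from low counts, and their edgeR mean of −1.06 moved to −0.56 without control 2. Of the other tested genes of the neutrophil list, S100a8 was at −1.33 and Ncf4 at −0.32, while Ceacam1 at 0.52 and Il1r2 at 0.44 went the other way. A treatment effect on inflammasome genes remains a hypothesis with no separate test here.

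Ccl27a, Itgb4 and F2rl1 are epithelial genes, and a larger share of epidermis in the treated samples might raise them. The 8 other epithelial genes tested had a mean of −0.06 (SE 0.05, edgeR mean −0.05), so no even rise of epithelial genes was seen. Their edgeR values ranged from −0.58 for Cxcl14 to 0.51 for Cdh1 (SD 0.40 between genes), with Itga6 at 0.35, Lcn2 at −0.39 and Muc1 at −0.45. The 3 genes were named because they rose, so that the others lay below them was largely fixed by that choice. A larger share of epidermis therefore stays open. TMM, median-of-ratios and total count scaling left the median of all tested genes at −0.055, −0.028 and 0.116, against −0.038 with housekeeping scaling. Under them the mean of the 3 genes lay between 0.84 and 1.01. Such small changes of scale cannot exclude housekeeping scaling as a cause. With positive control scaling, which leaves differences in RNA amount in place, the 3 genes were at 0.23, 0.13 and 0.36 and did not pass. The median of all genes was then −0.67. A treatment effect on the level per epithelial cell or a change in another cell type stays open and untested.

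The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 38 genes, as many as any (1 of 10 splits), and the highest other split gave 0. It gave 3 lists, and 4 of the 10 splits gave as many, the highest other giving 8. The number of lists past the threshold with the preset correlation therefore does not set the real split apart, and which lists passed in the other splits was not compared.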

How the results depend on the processing

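The alternatives of thinned counts and of samples left out with the count minimum of all samples kept were chosen after the data were seen. All 38 called genes that could be tested kept their sign under each of the 20 alternatives, but not their calls, and Fn1 passed in 18 of 20. For left-out samples, other count minima, DESeq2, limma and the replicate block the kept sign was fixed or nearly so in advance. These used the housekeeping scaling, under which the groups of these genes did not overlap. The number past the threshold was 54 with TMM (16 higher, 38 lower), 54 with median of ratios (17, 37), 60 with total count (30, 30), 244 with positive control probes (1, 243), 69 with DESeq2 (21, 48), 9 with limma on log2 scaled counts (2, 7) and 9 with limma on the deposited values (2, 7). It was 36 with the median housekeeping ratio, 43 with no count minimum, 32 with a minimum of 50, 39 with the minimum set by negative probes, 36 with background subtracted and 38 with thinned counts, 30 of them shared. Leaving out samples gave 0 to 36 genes, 0 to 4 higher and 0 to 32 lower, with 107 to 125 at an unadjusted p under 0.05. Fewer samples weaken the test, and which calls depend on a sample for other reasons was not tested. The median of all genes moved to 0.116 with total count and −0.674 with positive control scaling. Without control 2 Cxcl2 fell below the count minimum, and with the minimum of all samples kept it was at −2.11. Lists past the threshold numbered 7 with no count minimum (adhesion and angiogenesis downward, T cells and cytotoxic cells upward, besides the other 3), 0 with an estimated correlation and 0 with fry. With the replicate number as a block 30 genes passed, 3 higher and 27 lower, 28 of them shared. Same-numbered samples correlated at −0.08, 0.08 and 0.21 in their deviations from group means, and other pairs at −0.31 to 0.22. Deviations of 3 samples from their own mean depend on each other, so these values cannot tell whether the numbers pair the samples. For results other than these counts and medians, 2299 values stayed on the same side of the threshold, 286 fell below it, 134 rose past it and 63 changed direction.

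With positive control scaling Egr3 turned to −0.009, Cd274 to −0.14, Ciita to −0.012, Ctss to −0.34, Csf1 to −0.33, Ikbkb to −0.244, Traf2 to −0.274, Lgals3 to −0.114, Cd47 to −0.298, Cd3d to −0.045, Ctsw to −0.008, Ccr4 to −0.072, Blnk to −0.265, Ctla4 to −0.542, Cxcl12 to −0.602, Vim to −0.367, Cfd to −0.107, Cd55 to −0.013, C2 to −0.027, Cd3eap to −0.408, Gata3 to −0.093 and Nfatc1 to −0.008, each while the median of all genes fell too. With thinned counts Ctla4 turned to −0.069, Cd4 to 0.306 and Cd68 to 0.013, and with total count scaling Cd4 to 0.005 and Cd68 to 0.011. Without 1 sample Ctla4 ranged from −0.308 to 0.363, Cd68 from −0.25 to 0.063 and Cxcl12 from −0.186 to 0.197. None of these genes was called in the comparison.

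The direction of the list test also turned for lists that did not pass, at these list medians. With positive control scaling they were −0.811 for chemokine ligands, −0.756 for the TNF superfamily, −0.921 for B cells, −0.952 for dendritic cells and −0.924 for mast cells. With no count minimum they were 0.012 for type I interferon and 0.005 for the TNF superfamily. With a minimum of 50 they were −0.105 for type I interferon, −0.312 for B cells and 0.019 for melanocytes. With the minimum set by negative probes they were −0.093 for type I interferon, −0.083 for interleukins, −0.083 for the TNF superfamily and −0.121 for B cells. Under the replicate block they were 0.165 for interleukins and −0.312 for B cells, with fry 0.113 for interleukins, and with thinned counts −0.135 for B cells. Without 1 sample medians ranged from −0.28 to 0.043 for type I interferon, −0.208 to 0.242 for MHC class II, −0.402 to 0.032 for chemokine ligands, 0.004 to 0.194 for interleukins, −0.281 to 0.056 for the TNF superfamily, −0.371 to −0.173 for B cells and −0.121 to 0.283 for melanocytes. The cause of these changes was not tested.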

Other observations

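The genes in this part were chosen after their values were seen, and none passed the threshold (edgeR adjusted p over 548 genes). Higher means in treated tumours were found for the following genes, which form no tested group. Il22ra2, the soluble interleukin-22 binding protein, was at 19.5 ± 9 in control and 69.0 ± 51.5 in treated samples (log2 fold change 1.85, and 1.16 without treated 2, adjusted p = 0.072), Ccl19, a ligand of the homing receptor CCR7, at 152 ± 64.7 and 360 ± 149 (1.24, adjusted p = 0.0711), and Ccl20, which attracts CCR6-bearing cells, at 1.13 (1.74 without control 2, adjusted p = 0.146). Il18r1, a chain of the interleukin-18 receptor, was at 0.92 (adjusted p = 0.0799), Sigirr, an inhibitor of interleukin-1 family signalling, at 0.96 (adjusted p = 0.0681), Gata3 at 0.52 (adjusted p = 0.0779), Nfatc1 at 0.64 (adjusted p = 0.0681) and Nfatc2 at 0.79 (adjusted p = 0.072). Gata3 and Nfatc1 turned to −0.09 and −0.01 with positive control scaling.

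Among genes with lower means in treated tumours, Spp1, the matrix cytokine osteopontin, was at 252 ± 59.6 and 111 ± 52.7 (−1.20, adjusted p = 0.0539), Itga1, a collagen-binding integrin chain, at −1.05 (adjusted p = 0.0545), the C3a receptor gene C3ar1 at −0.86 (adjusted p = 0.0536), Raet1, a ligand of the NKG2D receptor, at −1.26 (adjusted p = 0.0539) and Il1rl1, the interleukin-33 receptor, at −1.37 (−0.77 without control 2, adjusted p = 0.072). Cxcl5 and Trem1 were at −2.88 (SE 1.03, adjusted p = 0.121) and −2.30 (SE 0.89, adjusted p = 0.156), values carried by control 2, without which they were at −0.73 and −0.91, and the prostaglandin synthase gene Ptgs2 at −0.90 (adjusted p = 0.111).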
